A study of Mus musculus with 2 samples.

How the data were processed

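Single-cell RNA-seq data of liver CD4+ T cells were used from 2 libraries of 1 group each, labelled cGVHD and no GVHD, both labelled day 60. Per the labels, cells were purified by fluorescence-activated sorting and libraries were made with the 10x Genomics Chromium Single Cell 5' kit. The deposited matrices hold UMI counts per gene and barcode, not normalized, made by the authors with Cell Ranger 3.1.0 on the mm10 build, per the submitters' processing notes. The annotation release behind the counts is not given in the sources used here. Each deposited table had 27998 gene rows and no rows of T cell receptor or immunoglobulin segments, so V-beta usage was not analysed here. The lowest barcode total was 500 UMIs in both libraries.

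Barcodes with at least 500 genes, at least 1000 UMIs and at most 10% mitochondrial UMIs were kept, which left 7245 cells of the library labelled cGVHD and 12450 of the other. Doublets were scored per library with Scrublet in scanpy 1.11.5. Its automatic threshold marked 0% of cells in both libraries, so the fallback fixed in the design was used and the highest-scoring cells were removed at 0.8% per 1000 cells. This removed 420 and 1240 cells and left 6825 and 11210. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 over both libraries gave 19 clusters. No correction between libraries was applied, and several clusters came almost wholly from 1 library, so such a cluster can be that library and not a cell type. Cluster sizes were therefore not compared between libraries.

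Clusters were named "X-like" from marker lists. A name needed at least 3 of its markers detected in at least 10% of cells at 1.5 times the level in all other cells, with 2 or more among the top 10 genes by fold and 1 or more among the top 5. These rules for applying the markers were set after the data were seen, over several rounds of clustering and naming, and 11 of 19 clusters were named. The T cell compartment left out 1 cluster with myeloid markers, with 88 cells in the library labelled cGVHD and 54 in the other, and held 6737 and 11156 cells.

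UMI counts were summed per library over the T cell compartment and divided by the total (CPM). Ratios are the library labelled cGVHD over the library labelled no GVHD, on the log2 scale, with exact conditional (Clopper-Pearson) 95% intervals. Sums have exact Poisson intervals and shares exact binomial (Clopper-Pearson) intervals. For a ratio against a count of 0, that count was set to a floor of 3 counts per library. All of these cover counting error only, since cells are not replicates and there was 1 library per group. No test of a difference between the groups was run. A gene counted as higher or lower at a CPM of at least 50 in the higher library and a ratio of at least 2.

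The marker lists, gene lists, rule for named genes, comparisons and most alternatives were fixed before the data were examined. The rule for named genes took the 15 genes highest and the 15 lowest in the library labelled cGVHD, ranked by the bound of the counting interval nearest 0, with the same direction at 2 times under TMM scaling and with cells weighted equally. Mitochondrial, ribosomal protein, haemoglobin, receptor segment, model-named, Xist and Y-linked genes were left out. It added a panel of genes and up to 4 members of each gene list with the largest absolute ratio at a CPM of at least 20. Prf1, Isg20, Lef1, Klf2, S1pr1 and Il13 are further list members, and Nrp1, Trnp1, Ecm1 and Socs2 lead the ratios within their class by the rule of the 15 genes applied there; these were chosen after their values were seen. Of the genes the rule names, 1 is left out on purpose, and the text does not print a value for each of the others. Coordinates are 1-based, from GENCODE release M21 by gene ID, on the mm10 build; 27722 of the 27998 IDs were found there.

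There were 20 gene lists. Each list's median log2 ratio, over members with at least 10 CPM in either library, was placed among 10000 random lists of the same size matched on mean expression. A list stood apart below percentile 2.5 or above 97.5, and a member counted as higher or lower at a ratio of 1.5. Shares of cells with a UMI were computed after thinning each cell to 1300 UMIs, the 10th percentile of the shallower library rounded down to a whole 100; 551 cells of the library labelled cGVHD and 625 of the other had fewer UMIs and were left out. Ratios within a class were computed for classes with at least 100 cells in each library.

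The ratio and list computations were tested on simulated counts for the T cell compartment comparison, over 2884 genes with 3-fold changes. Of 100 genes made higher and 100 made lower, 100 and 100 were recovered, 0 unchanged genes were called, and 95.0% of intervals held the true ratio. A list of raised genes lay at percentile 100 and a list of unchanged genes at 54.3, and the list rule called 2% of 200 unchanged lists. The simulated genes were independent Poisson counts, so this checks the computation only. The 2% does not cover lists of genes that vary together. Alternatives for scaling, cell filters, doublets, thinning, gene filters and clustering were tried. Populations without the naive-like clusters, without the cells under 2500 UMIs, without a set of cells defined by 3 gene models, and without both the first and the last, were added after seeing the data. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, igraph 0.11.9, scikit-learn 1.9.0, R 4.3.3 and edgeR 4.0.16, which gave the TMM factors of 0.928 for the library labelled cGVHD and 1.08 for the other.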

Results

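Liver CD4+ T cells were profiled by droplet-based single-cell RNA sequencing in a mouse model of chronic graft-versus-host disease (cGVHD), in which T cells of a transplanted graft attack the tissues of the recipient. For the cGVHD mice, the series text states that BALB/c recipients were given grafts from B6 donors; it does not state what the no GVHD mice received. Both libraries are labelled day 60. Cells with the donor MHC molecule H2Kb, a T cell receptor and CD4 had been sorted before loading, as the series text states for the cGVHD mice; the labels call the cells of both libraries donor CD4+ T cells. There was 1 library labelled cGVHD and 1 labelled no GVHD, so no difference below has a replicate check and no p-value is given. The intervals cover counting error only. The library labelled cGVHD held 9248 barcodes and 32136660 UMIs, with a median of 3060 UMIs and 1213 genes per barcode. The library labelled no GVHD held 13872 barcodes and 66037074 UMIs, with medians of 3900 UMIs and 1652 genes. After filtering, the T cell compartment held 6737 and 11156 cells, in that order, with 27612014 and 55914741 UMIs. Each library is named by its label throughout, because the genes of naive cells were higher in the one labelled cGVHD.

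The main comparison asked how donor CD4+ T cells in the liver differed between the library labelled cGVHD and the one labelled no GVHD. Genes of naive, recirculating T cells were higher in the library labelled cGVHD. Ccr7, the chemokine receptor for entry into lymph nodes, stood at 712 CPM (95% exact Poisson interval 702 to 722) against 28.1 CPM (26.7 to 29.5). Genes of activated and tissue-dwelling cells were lower in that library. Cxcr6, a chemokine receptor of liver-resident lymphocytes, stood at 79.5 CPM (76.2 to 82.9) against 658 CPM (651 to 665), and Ccl5, a chemokine of effector T cells, at 799 CPM (789 to 810) against 6346 CPM (6326 to 6367).

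Of 3001 genes with at least 50 CPM in 1 or both libraries, 106 were at least 2 times higher in the library labelled cGVHD and 249 were at least 2 times lower. The median log2 ratio of these 3001 genes was -0.25, and TMM scaling shifted all log2 ratios by 0.22. With TMM scaling 151 genes were higher and 171 lower, so that the higher genes made up 46.9% of the called genes in place of 29.9%. With the total taken without mitochondrial and ribosomal protein genes, 187 genes were higher and 254 lower, and the higher genes made up 42.4%.

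**Figure D1:**
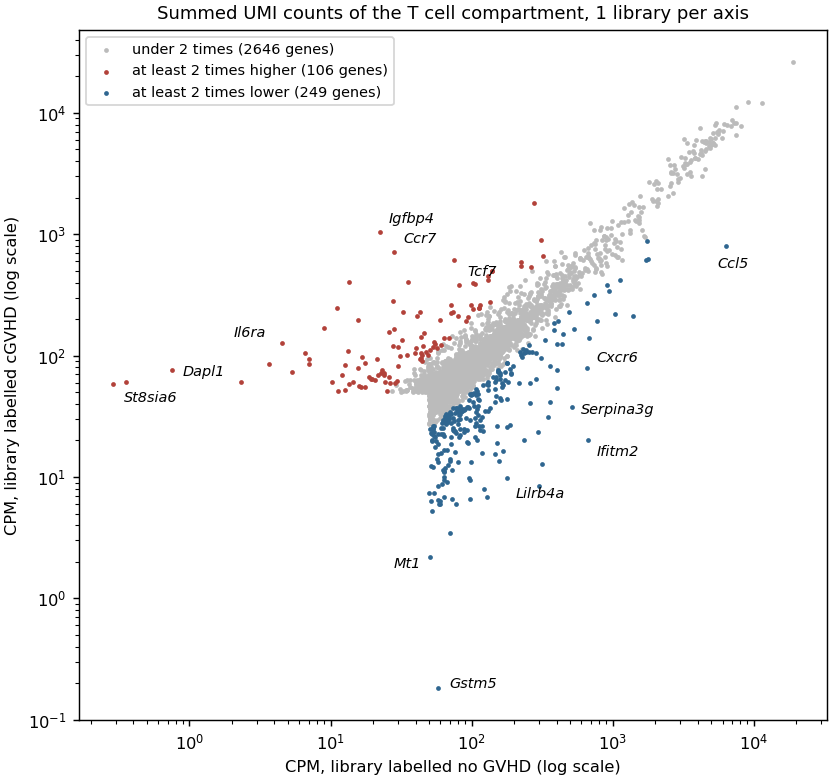
Each point is a gene with at least 50 CPM in 1 or both libraries, with its summed CPM in T cells of the library labelled no GVHD on the x axis and of the library labelled cGVHD on the y axis, both on log scales. Red points are the 106 genes at least 2 times higher in the library labelled cGVHD and blue points the 249 genes at least 2 times lower; Ccr7 and Igfbp4 lie far above the diagonal, and Gstm5, Ifitm2 and Cxcr6 far below it.

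The 15 genes that led the higher side included St8sia6, Dapl1, Igfbp4, Il6ra, Ccr7, Tdrp, Actn1, Pdlim4, Cmah, Tubb2a, Atp1b1, Nsg2, Ly6c1 and Bach2. The log2 ratio was 7.68 for St8sia6 (95% counting interval 6.98 to 8.49), a sialyltransferase gene on chromosome 2 at 13651021 to 13794064 (mm10, minus strand, ENSMUSG00000003418). It was 5.53 for Igfbp4 (5.45 to 5.61), an insulin-like growth factor binding protein, and 4.82 for Il6ra (4.63 to 5.01), the interleukin-6 receptor chain that naive T cells carry. Igfbp4 (ENSMUSG00000017493) lies on chromosome 11 at 99041244 to 99054392 and Ccr7 (ENSMUSG00000037944) on the same chromosome at 99144196 to 99155077. The log2 ratio was 3.61 for Bach2 (3.45 to 3.76), a repressor of effector differentiation.

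The 15 genes that led the lower side were Gstm5, Ifitm1, Ifitm2, Ifitm3, Mt1, Lilr4b, Lilrb4a, Serpina3f, Sytl3, Serpina3g, Tmem176b, Csf1, Ctla2a, Mdfic and Cish. Gstm5, a glutathione S-transferase gene on chromosome 3 at 107895821 to 107898686 (mm10, plus strand, ENSMUSG00000004032), had 5 UMIs in the library labelled cGVHD and 3253 in the other, a log2 ratio of -8.33 (-9.95 to -7.10). Ifitm1, Ifitm2 and Ifitm3, interferon-induced transmembrane genes that lie near each other on chromosome 7, had log2 ratios of -5.15 (-5.34 to -4.96), -5.03 (-5.15 to -4.91) and -4.62 (-4.78 to -4.47). The log2 ratio was -4.55 for Mt1 (-4.94 to -4.18), a metallothionein that binds zinc and copper. It was -3.69 for Csf1 (-3.92 to -3.46), a growth factor of macrophages, and -3.46 for Cish (-3.56 to -3.36), an inhibitor of cytokine receptor signalling. Lilr4b and Lilrb4a, Serpina3f and Serpina3g, and the Ifitm genes have near copies that can share reads, so the values are uncertain for each gene alone.

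Gene lists gave the same division. Of the 14 measured genes of naive and quiescent T cells, 13 were at least 1.5 times higher and 0 were lower in the library labelled cGVHD. Their median log2 ratio was 2.88, at percentile 100 among 10000 random lists of the same size matched on mean expression. Lef1, Klf2 and S1pr1, which hold T cells in a quiescent and recirculating state, had log2 ratios of 3.04, 2.71 and 2.42. The type I interferon list was also higher, with a median of 1.26 (percentile 100) and 8 of 11 members higher. Within naive-like cells it did not stand apart (0.12, percentile 82.7). Usp18 and Ifi27l2a, both induced by type I interferon, had log2 ratios of 2.58 (2.35 to 2.82) and 1.55 (1.52 to 1.57), while Isg20 was lower at -0.82.

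The lists of effector programmes were lower in the library labelled cGVHD. Of 12 Th1 genes 11 were lower, with a median of -2.30 (percentile 0). They included Tbx21, the Th1 transcription factor, at -2.27 (-2.40 to -2.14), and Ifng, its cytokine product, at -2.22 (-2.33 to -2.10). Of 13 cytotoxic genes 12 were lower (median -1.84), and Prf1, the pore-forming protein of cytotoxic granules, stood at -0.05, within the shift of TMM scaling. All 4 measured Th17 genes were lower (median -3.27), among them Tmem176a and Tmem176b at -3.23 and -3.67. Of 5 measured Th2 genes 3 were lower (median -1.94, percentile 0.40), led by the cytokine gene Il13 with 1 and 645 UMIs, a log2 ratio of -8.32 (-13.62 to -5.83). Outside the naive-like clusters the Th2 list did not stand apart (0.013, percentile 53.8). Within proliferating-like cells it stood apart on the higher side (0.89, percentile 99.8), with 3 of 4 measured members higher and 1 lower. Of 10 inhibitory receptor and exhaustion genes 9 were lower (median -1.98), including Pdcd1, which encodes PD-1, at -2.53 (-2.65 to -2.43) and Tigit at -2.67 (-2.76 to -2.59). Outside the naive-like clusters the median of this list was -0.52 (percentile 0), with 4 of 10 members lower and 1 higher.

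Genes of tissue residence and tissue injury followed the effector lists. Of 15 residency genes 10 were lower and 1 higher (median -1.43), with Itga1, a collagen-binding integrin, at -3.55 (-3.89 to -3.23) and Bhlhe40 at -3.12. Outside the naive-like clusters the residency list had a median of -0.38 (percentile 0.03), with 7 members lower and 2 higher. Within proliferating-like cells it did not stand apart (-0.21, percentile 5.9). Cd69, a marker of both activation and residence, was close to level at 0.24 (0.19 to 0.28). Of 11 cytokines of tissue injury 10 were lower (median -1.45), including Il2 at -3.24, Csf2 at -3.31 and Tnfsf11 at -3.16. Of 8 chemokine receptors 6 were lower (median -2.27) and Ccr7 alone was higher, with Ccr2 at -2.81 and Ccr8 at -2.89. The chemokine receptor list did not stand apart outside the naive-like clusters (0.084, percentile 70), nor within proliferating-like (0.039) or regulatory T-like cells (-0.0029). In the activation list 9 of 14 members were lower and 0 higher (median -1.06), with Cd44 at -1.98 and Il2ra, the high-affinity interleukin-2 receptor chain, at -2.32. This list did not stand apart outside the naive-like clusters (0.057, percentile 47.4). Its median was higher within naive-like (0.32, percentile 99.1) and proliferating-like cells (0.21, percentile 97.9), with members on both sides. In naive-like cells 5 of 10 members were higher and 4 lower, and in proliferating-like cells 4 of 14 were higher and 2 lower.

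Several lists moved less or held members on both sides. The follicular helper and B cell help list had a median of -0.57 (percentile 0.76), with Tox2 lower at -2.67 and Slamf6 higher at 1.71. After thinning of every cell to 1 number of UMIs this list no longer stood apart from the random lists. Outside the naive-like clusters it did not stand apart either (0.20, percentile 91.75), nor within regulatory T-like cells (-0.19). It stood apart on the higher side within naive-like (0.47, percentile 99.4) and proliferating-like cells (0.50, percentile 99.96). The regulatory T cell list had a median of -0.81 (percentile 0.02) with 7 of 12 members lower, but outside the naive-like clusters it stood apart on the higher side (0.45, percentile 99.96), and in proliferating-like cells as well (0.97, percentile 100). Over all T cells its transcription factor gene Foxp3 was higher at 1.44 (1.28 to 1.59). The adhesion list had a median of -0.65 (percentile 0.03), with Itga1 lower, Ly6c1 higher at 3.53 and the related Ly6c2 lower at -1.89. Selplg, which encodes the P-selectin ligand PSGL-1, stood at -0.02 (-0.05 to 0.01) and at 0.20 with TMM scaling. Outside the naive-like clusters the adhesion list stood apart on the higher side (0.26, percentile 98.4), as it did within naive-like (0.30), proliferating-like (0.34) and regulatory T-like cells (0.26). Its members lay on both sides, with 6 of 14 higher and 2 lower outside the naive-like clusters and within proliferating-like cells alike. In naive-like cells 2 of 11 were higher and 1 lower, and in regulatory T-like cells 2 of 13 were higher and 3 lower. The glycolysis and hypoxia list had a median of -0.55 (percentile 0.25), and its exception was Pdk1, a pyruvate dehydrogenase kinase, at 1.98. Outside the naive-like clusters this list did not stand apart (0.064, percentile 60.7), nor within naive-like (-0.23) or proliferating-like cells (-0.13). Within regulatory T-like cells it was lower (-0.33, percentile 0.32). The stress and dissociation list was higher, with a median of 0.44 (percentile 99.98), and Fos, Jun and Dnajb1, which respond to handling of cells, stood at 1.80, 1.86 and 1.10. The lists of T cell receptor signalling (median -0.45, percentile 3.78), interferon gamma response (0.01, percentile 95.6), proliferation (-0.21, percentile 62.9) and oxidative phosphorylation (-0.21, percentile 34.3) did not stand apart from random lists. Within classes, T cell receptor signalling stood apart in opposite directions, at 0.50 (percentile 99.8) in naive-like and -0.84 (percentile 0) in regulatory T-like cells. Proliferation was higher in proliferating-like cells (0.36, percentile 100) and oxidative phosphorylation lower in naive-like cells (-0.23, percentile 1.96). The interferon gamma response list was lower in each class, with medians of -0.71 (percentile 0) in naive-like, -0.34 (percentile 0.31) in proliferating-like and -0.31 (percentile 1.58) in regulatory T-like cells. Its members Iigp1 and Gbp2 were among the top genes of cluster 5, a naive-like cluster. Cluster 5 held 1043 of the 5476 naive-like cells of the library labelled cGVHD and 263 of the 330 of the other. The naive-like median of this list was thus not set apart from the mix of clusters.

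**Figure D2:**
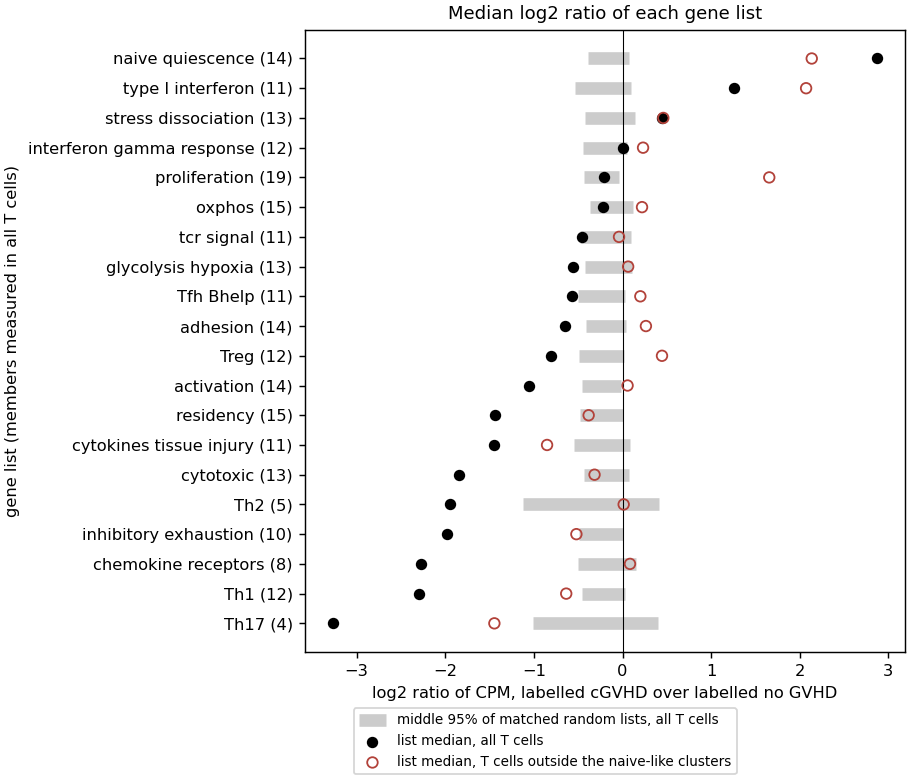
For each gene list, the x axis gives the median log2 ratio of CPM, library labelled cGVHD over library labelled no GVHD, with the number of measured members beside the list's name on the y axis. Black points are all T cells, grey bars the middle 95% of matched random lists, and open red points the T cells outside the naive-like clusters; the naive list lies at 2.88 and the Th17 list at -3.27.

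Shares of T cells with a UMI, after each cell was thinned to 1300 UMIs, followed the summed counts. Ccr7 was detected in 54.8% of 6186 cells of the library labelled cGVHD (exact binomial interval 53.5 to 56.0) and in 2.40% of 10531 cells of the other (2.12 to 2.71). The corresponding shares were 39.7% (38.4 to 40.9) and 10.0% (9.48 to 10.6) for Tcf7, a transcription factor of naive and memory precursor cells. Ccl5 was detected in 9.25% (8.54 to 10.00) and 79.2% (78.4 to 80.0), and Cxcr6 in 5.12% (4.59 to 5.70) and 53.3% (52.3 to 54.2). Pdcd1 was detected in 2.25% (1.89 to 2.65) and 16.7% (16.0 to 17.4). Selplg, whose protein level is used to divide memory CD4+ T cells in this disease, was detected in 47.9% (46.7 to 49.2) and 49.3% (48.4 to 50.3). Without thinning, Ccr7 was detected in 75.4% and 4.87%, and Ccl5 in 12.8% and 90.7%.

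Background was read in cell classes that should lack a gene, and it differed between genes and libraries. The cluster outside the T cell compartment had 82 thinned cells (median 5507 UMIs) in the library labelled cGVHD and 49 in the other. Cd3e was detected in most of its cells, so it is a poor measure of free RNA. Ccl5 and Ccr7 were each detected in 18.3% of the 82, and in the 49 cells of the other library Ccl5 was detected in 87.8% and Cxcr6 in 55.1%, as often as in its T cells. In the naive-like cells, which should lack Ccl5 and Cxcr6, these were detected in 1.85% and 0.258% of 5038 thinned cells of the library labelled cGVHD (median 3883.5 UMIs before thinning). In 310 naive-like cells of the other library (median 4868.5 UMIs) they were detected in 24.8% and 3.23%. Ccr7 was detected in 0.773% of the 10221 cells outside the naive-like clusters of the library labelled no GVHD (median 4347 UMIs). Foxp3 was detected in 2.02% (1.69 to 2.40) of T cells of the library labelled cGVHD and 0.798% (0.637 to 0.987) of the other, and in 0.457% and 0.323% of their naive-like cells. Csf2, a growth factor of myeloid cells, was detected in 0.113% (0.0455 to 0.233) and 1.76% (1.51 to 2.03). For Cxcr5, the follicular homing receptor, the shares were 0.178% (0.0888 to 0.318) and 0.332% (0.232 to 0.462), with overlapping intervals. Without thinning they were 0.520% (0.362 to 0.722) and 0.950% (0.779 to 1.15), and the log2 ratio of its summed CPM was -0.53 (-1.09 to -0.0013).

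**Figure D3:**
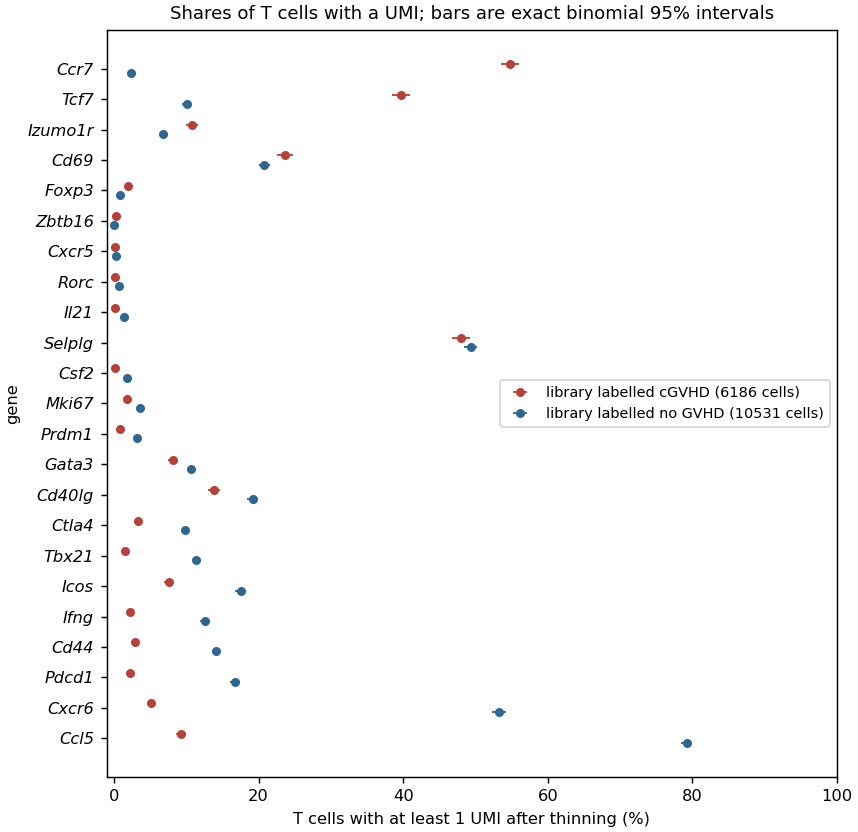
The x axis gives the percentage of T cells with at least 1 UMI of each gene on the y axis after every cell was thinned to 1300 UMIs; red points are the 6186 cells of the library labelled cGVHD, blue points the 10531 cells of the library labelled no GVHD, and bars the exact binomial intervals. Ccr7 and Tcf7 lie to the right in the library labelled cGVHD, and Ccl5, Cxcr6 and Pdcd1 in the other.

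The naive-like clusters made up most of the library labelled cGVHD, so the same comparison was made in the other T cells, a choice made after the data were seen. There were 1261 such cells in the library labelled cGVHD, of which 460 were regulatory T-like, and 10826 in the other, of which 201 were. Here 135 genes were at least 2 times higher and 71 at least 2 times lower, and 42 and 62 of these were among the 106 and 249. Ccr7 remained higher, with a log2 ratio of 4.55, and Foxp3 stood at 3.26. Ccr7 was detected in 17.4% of the thinned cells outside the naive-like clusters of the library labelled cGVHD. In that library's cells outside the T cell compartment the share was 18.3%. Free RNA was thus not set apart from expression for Ccr7 or the naive list. Outside the naive-like clusters the type I interferon list had a median of 2.07 (percentile 100), the naive list 2.14 (percentile 100) and the stress and dissociation list 0.46 (percentile 99.9). The interferon-response-like cluster held 104 of the 1261 cells and 80 of the 10826. The type I interferon median was thus not set apart from the mix of clusters, and within proliferating-like cells it was 0.91 (percentile 100). Of 19 cell cycle genes 16 were higher outside the naive-like clusters (median 1.66), including Mki67 at 1.66 and Ube2c at 2.44. The proliferating-like cluster held 225 of the 1261 cells and 529 of the 10826. Within that cluster the median of the list was 0.36, with 1 of 19 members higher. The Th1 list had a median of -0.64 (percentile 0). Of the 1261 cells, 180 had UMIs of at least 2 of the gene models Gm10260, Gm8730 and Gm6576, which 0 of the 10826 had, and the origin of these cells is open. Without them the median was -0.93 for the Th1 list, -0.69 in place of -0.32 for the cytotoxic list and 2.42 for the type I interferon list.

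Regulatory T-like cells, 460 in the library labelled cGVHD and 201 in the other, formed a single cluster, whose make-up was not shown to be the same in both libraries. Foxp3 was detected in 13.3% (10.3 to 16.9) and 27.9% (21.8 to 34.7) of its thinned cells, and at a resolution of 2 the class held 135 and 121 cells. In the library labelled cGVHD the naive and quiescence list was higher in them (median 1.33, percentile 100) and the activation list lower (-0.88, percentile 0). The log2 ratio was 2.12 for Ccr7 (1.73 to 2.54) and 3.74 for Igfbp4 (2.95 to 4.67). Ccr7 was detected in 16.1% of the 435 thinned regulatory T-like cells of the library labelled cGVHD. This is no more than the 18.3% in its cells outside the T cell compartment, so free RNA was not set apart. The log2 ratio was 1.96 for Nrp1 (1.58 to 2.35), a semaphorin receptor found on thymus-derived regulatory cells, a gene chosen after its value was seen. Lower genes were Il2ra at -2.28 (-2.69 to -1.88), Tnfrsf4, which encodes the costimulatory receptor OX40, at -2.29 (-2.44 to -2.14), and Ccr8 at -2.65 (-3.03 to -2.28). Foxp3 itself was lower at -0.81 (-1.03 to -0.59), with 338 and 340 UMIs. The regulatory T cell list had a median of -1.56 (percentile 0) with 10 of 14 members lower, and the type I interferon list one of 1.02 (percentile 100). The stress and dissociation list was also higher in them (0.80, percentile 100), with 9 of 14 members higher. In these cells 47 genes were at least 2 times higher and 91 at least 2 times lower out of 3241.

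Naive-like cells numbered 5476 and 330, and different clusters held most of them: clusters 3, 4, 5 and 8 in the library labelled cGVHD and cluster 5, with 263 cells, in the other. Within the class, 51 genes were at least 2 times higher and 58 at least 2 times lower in the library labelled cGVHD, out of 2483. St8sia6 was higher at 3.64 (2.71 to 4.77), while Ccr7 differed by 0.25. The stress and dissociation list was higher within the class (0.71, percentile 100), with 10 of 13 members higher. Of the genes chosen after their values were seen, Trnp1 was lower at -9.21 (-12.28 to -7.31), on 2 and 87 UMIs, and so were Ecm1 at -3.26 (-3.41 to -3.10) and Socs2, a feedback inhibitor of cytokine signalling, at -4.60 (-5.15 to -4.06). Ecm1 was among the top 10 genes of cluster 5, so its ratio was not set apart from the mix of clusters. Proliferating-like cells numbered 225 and 529. In them Foxp3 was higher at 2.30 (2.03 to 2.58) in the library labelled cGVHD. Ifitm1 was lower at -6.11 (-7.42 to -5.06) and Ccl5 at -2.70 (-2.81 to -2.60). Ccl5 was also lower in naive-like cells, at -3.70 (-3.89 to -3.50), where its UMIs were read as background, so free RNA was not set apart from expression in these ratios.

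**Figure D4:**
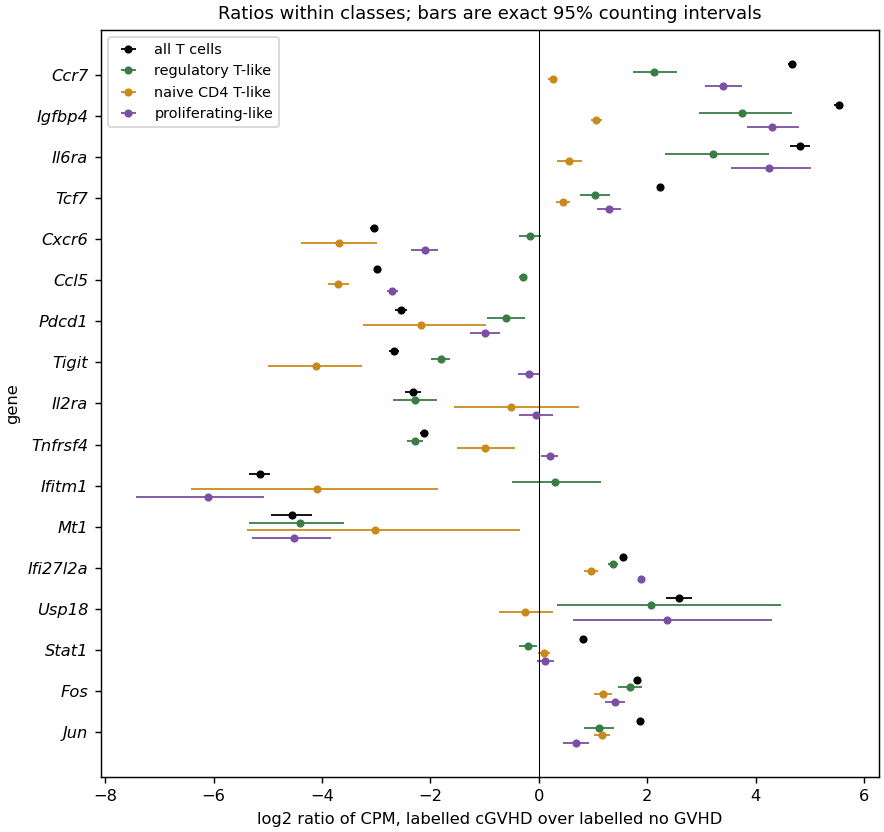
The x axis gives the log2 ratio of CPM, library labelled cGVHD over library labelled no GVHD, for the genes on the y axis in all T cells (black), regulatory T-like (green), naive-like (orange) and proliferating-like cells (purple), with 95% counting intervals; a class without UMIs of the gene in 1 library has no point. Ccr7 lies at 4.66 in all T cells, 2.12 in regulatory T-like, 3.40 in proliferating-like and 0.25 in naive-like cells.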

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

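The look at cells outside the T cell compartment, and its genes, were chosen after the clusters were seen, and no test of a cause was run. These cells drew attention as a signal in data that the comparisons did not use. A cluster with myeloid genes held 88 cells of the library labelled cGVHD and 54 of the library labelled no GVHD, above the 3 cells that a count of 0 allows. In these cells Lyz2, a lysozyme gene of myeloid cells, stood at 6720 and 1628 CPM, against 1.63 and 0.393 CPM in the T cells of the same library. S100a8, a neutrophil gene, stood at 469 and 11431 CPM, from 4.55% and 16.7% of the cells. Cd3e, a gene of the T cell receptor complex, was detected in 71.6% and 83.3% of them. The sort for a T cell receptor and CD4 would remove myeloid cells, and whether these are doublets or cells past the sort was not tested.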

How the results depend on the processing

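The alternatives without the naive-like clusters, without the cells under 2500 UMIs and without the gene model cells, and without the first and last together, were chosen after seeing the data. Over the planned cell filters, the equal weighting of cells and the thinning, the number of higher genes ran from 106 to 115 and of lower genes from 243 to 296; with TMM scaling they were 151 and 171. Both numbers moved by over 1.5 times with a CPM of at least 10 (272 higher and 662 lower), with no CPM filter but at least 10 UMIs (998 and 2063) and with a ratio of 1.5 (205 and 541), settings that admit more genes by construction. The number of higher genes was 187 with the total taken without mitochondrial and ribosomal protein genes. A smaller total raises every CPM, so this setting also admits more genes by construction. It moved the median log2 ratio of the genes tested from -0.25 to -0.09. Outside the naive-like clusters 71 genes were lower, or 80 with the gene model cells left out too, and the cause was not tested.

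Of the list medians under the alternatives, 229 kept both their direction and their side of the percentile limits. Another 10 changed sign without standing apart: interferon gamma response, near 0, under 6 alternatives, proliferation and oxidative phosphorylation with TMM scaling, and oxidative phosphorylation outside the naive-like clusters, with and without the gene model cells, at 0.22 in both. The T cell receptor signalling list stood apart at -0.51 with a mitochondrial limit of 5% and at -0.52 without the gene model cells. The interferon gamma response list stood apart at 0.19 with members of at least 50 CPM, a setting that 19 of the 20 lists allowed. The follicular helper list no longer stood apart at -0.52 with thinned cells. Outside the naive-like clusters 9 list medians turned from below to above 0, oxidative phosphorylation and 8 others: activation 0.057, Th2 0.013, follicular helper 0.20, regulatory T 0.45, proliferation 1.66, glycolysis 0.064, chemokine receptors 0.084 and adhesion 0.26, of which regulatory T, proliferation and adhesion stood apart there. With the gene model cells left out too, activation did not turn and no longer stood apart, at -0.082, while 7 turned: Th2 0.15, follicular helper 0.20, regulatory T 0.48, proliferation 1.70, glycolysis 0.075, chemokine receptors 0.16 and adhesion 0.25. With those cells kept, 16 of the named genes also turned, among them Icos, Rora and Maf, each at least 2 times lower over all T cells, to 0.17, 0.037 and 0.20, and Ctla4 to 0.80. For these lists and genes the cause was not tested. Of the named genes, 90 moved beyond their counting interval with TMM scaling, which shifts every gene alike, and 58 with equal weights. Of the shares with a UMI, 47 moved without thinning and 0 over all kept cells. Of the class shares under other clustering or cell filters, 30 moved beyond their interval and 32 did not, and the Th17-like class had no value at a resolution of 0.5. Both V-beta alternatives were not run. No paired analysis was possible because each group has 1 library. Depth limits genes with few UMIs, such as Il21 with 49 and 685 UMIs.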

Other observations

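The tests of low-UMI cells used a population chosen after the data were seen, and the tests of swapped labels, doublets and CD8 T or NK cells were chosen after the result was seen. In regulatory T-like cells the chemokine genes Ccl1, Ccl3 and Ccl4 were lower in the library labelled cGVHD, with log2 ratios of -6.25 (95% counting interval -8.55 to -4.67), -3.42 (-4.35 to -2.60) and -4.87 (-5.41 to -4.37). Irf8, a transcription factor induced by interferon, was lower at -3.46 (-4.01 to -2.95), while Itgb1, an integrin chain, was higher at 1.68 (1.53 to 1.83). Ccl1, Ccl3, Irf8 and Itgb1 were chosen after their values were seen. Ccl1, Ccl3 and Ccl4 were also among the top genes of cluster 9, which is unnamed. It held 51 cells of the library labelled cGVHD and 955 of the other. Over all T cells Ccl4 stood at 53.7 CPM in the library labelled cGVHD and 404 CPM in the other. Free RNA was thus not set apart from expression in the regulatory T-like ratios of Ccl1, Ccl3 and Ccl4.

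Izumo1r, which encodes folate receptor 4, a protein of regulatory and anergic T cells, was higher in the library labelled cGVHD over all T cells at 0.87 (0.80 to 0.94) and lower in regulatory T-like cells at -1.14 (-1.35 to -0.93). Ctla4, an inhibitory receptor, was lower over all T cells at -0.96 (-1.05 to -0.86), higher outside the naive-like clusters at 0.80 (0.70 to 0.90), lower in regulatory T-like cells at -1.44 (-1.65 to -1.23) and higher in proliferating-like cells at 0.97 (0.78 to 1.15). Zbtb16, a transcription factor of innate-like T cells, had 50 UMIs in the T cells of the library labelled cGVHD and 2 in those of the other, a log2 ratio of 5.66 (3.73 to 8.75).

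Naive-marker genes were higher and effector genes lower in the library labelled cGVHD, although disease in this model is driven by activated T cells. With every cell thinned to 1 number of UMIs the naive and quiescence list kept a median log2 ratio of 3.02. Thinning keeps the expected proportions within each cell, and CPM is already divided by the total. This median could therefore hardly fall, and it does not decide on a difference in depth. Without the cells under 2500 UMIs the median of the list was 2.83. Cells with few UMIs add little to summed counts, so this median could hardly fall either. A limit on UMIs also does not mark dying cells, so the value does not decide on low-UMI and dying cells. Swapped labels stay open: they predict a median above 0, as deposited it was 2.88, but a true difference between the groups predicts this too, so no outcome of this test would have supported a swap over it. That difference is untested with 1 library per group, and no value independent of T cell state shows which library belongs to which label: the gene model cells described next set the libraries apart, but their origin is itself open.

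In the library labelled cGVHD, 183 T cells (2.72%, exact binomial interval 2.34 to 3.13) had UMIs of at least 2 of Gm10260, Gm8730 and Gm6576, against 0 of 11156 in the other library, which allows up to 0.0269%; this definition replaced a cluster after the clusters were seen. Median UMIs of 0.937 times those of the other T cells argue against doublets, and Cd4 at 1.27 times argues against CD8 T or NK cells as the whole set, although Cd8a stood at 320 against 12.7 CPM and 37 of the cells had Cd8a and no Cd4 UMIs. Cells of another mouse strain may be a source: H2-K1 and H2-D1 were expected below 0.5 times the other T cells, and their 1.51 times met the bound of 0.8 times that had been set in advance to count against it. That bound was set aside only after this result, because alleles of both strains are counted under 1 gene and because the nearest genes by shared 31-base words, Rps18, Rplp0 and Rps2, stood at 0.205, 0.493 and 0.531 times, genes looked at after the cells were seen. H2-Q1, another MHC class I gene, stood at 336 against 1.69 CPM; strain stays open, reads were not analysed here, and the sort for H2Kb would remove cells of the BALB/c recipient.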
